A study of Brassica napus with 6 samples.

How the data were processed

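Total RNA was isolated from roots with a plant RNA kit, biotin-labelled cRNA was made from it with a 3' amplification kit, and 1 array was hybridised per sample, per the labels' protocols. The platform annotation identifies the array as the Arabidopsis ATH1 design. Cross-species hybridisation lowers the signal wherever an oilseed rape transcript differs from the Arabidopsis probe, so a low signal here does not show a low transcript level. Raw scanner images and probe-level intensities were not used here, and scan dates and slides were not given in the sources used here, so no batch could be tested.

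The deposited table holds 1 value per probe set and array on a log2 scale. The log base was taken from the range of the values, 5.20 to 11.40 over the probe sets tested, and was not stated. R 2.7.2 is named in the submitters' processing notes. The background correction, normalisation and probe-set summary were not given in the sources used here. No further normalisation was applied. Array medians over all probe sets were held near 6.00 by the constant probe sets and so cannot show whether one was needed; over the varying probe sets they ran from 6.26 to 6.29. All 6 columns were matched to samples by name. The labels call the samples biological replicates of each group.

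The table has 22810 probe sets, of which 64 control probe sets were kept apart and 22746 tested. The annotation table gave 1 gene name for 13513 of these, several for 503 and none for 8730, which are unnamed here. No gene was named from a probe set with several. For a gene with several probe sets the brightest stood for the gene. To judge signal over background, 27 control probe sets for bacterial genes served as a reference; whether these transcripts were added is not given in the sources used here. Their means ran from 5.44 to 6.05, and 9686 tested probe sets (42.6%) and 1721 varying ones (70.9%) lay above the highest.

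Differences are cadmium with GSH minus cadmium alone, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The design, the lists of genes, the rule for named genes and most alternatives were fixed before the data were examined. The planned fit covered all 22746 probe sets. In that fit the prior variance was estimated at 4.06e-20, because most probe sets held a single value, so rounding differences could pass the test. A second fit, chosen after seeing the data, was therefore restricted to the 2428 probe sets that ranged over more than 0.01, and its prior variance was 0.00121. The gene values in the results come from the second fit; the log2 differences are the same in both. Of the constant probe sets, 636 were exactly equal on all arrays and 19860 ranged by under 0.000001 or were equal; 458 lay between that and 0.01.

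The rule for named genes took the 12 largest rises and 12 largest falls among adjusted calls with non-overlapping groups and 1 annotated gene, filled where too few passed by the smallest unadjusted p in each direction. Applied to the planned fit it would have named rounding differences, so it was applied to the second fit, where none passed and all 24 came from the smallest unadjusted p. From each list the rule took up to 4 members by p; only varying members are given values, and the others are described as constant.

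Lists were matched by locus or, where the annotation gives a symbol, by symbol, with the gene's neighbours by Entrez number on the same chromosome as the planned locus; GR1 and CCR2 were matched in this way. The chromosome criterion was loosened from a closer neighbourhood after seeing the data, which added LHCB4.1, a constant probe set. Members without a match, 363 of 409, were left out. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the lists. Neither camera nor fry was run on a list with fewer than 2 matched members. List loci were written from general knowledge of Arabidopsis genes. Another 4 lists were drawn up once the data had been seen and are reported only in the closing section.

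Alternatives were quantile normalisation, array median centring, leaving out the dimmer part of the probe sets, an intensity trend with robust eBayes, the replicate number as a block, 1 probe set per gene, a floor at each array's 10th percentile, a 2-fold threshold, a plain two-sample test, averaging a gene's probe sets and leaving out each array in turn. Other limits on the range, 0.0001 and 0.1, were added after seeing the data. With 3 arrays against 3, an exact permutation test of a single value cannot give a p under 0.1.

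The fit was tested on simulated data made from the means and spreads of the real probe sets, with 200 changed in each of 10 runs. For the 2428 varying probe sets, 87.9% of differences of 0.5 and 95.7% of differences of 1 were recovered, with 10.6 false calls per run. For all 22746 probe sets, 95.6% and 98.1% were recovered, with 12.1 false calls per run. Recovery there was all but fixed in advance, since 89.3% of the probe sets were constant and were simulated with a spread near 0. In the real fit of varying probe sets, AILP1 at -0.73 and 264809_at at -1.66 did not pass. The recovery therefore does not show that real differences of such sizes would be found. The simulated noise was normal and independent between probe sets, which real arrays need not be. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.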

Results

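The series measured transcript signal in roots of oilseed rape (Brassica napus, cultivar Nourin No.16) grown in hydroponics with cadmium. Plants, whose age the labels give as 4 weeks after germination in one field and as 2 to 3 weeks in the growth protocol, were kept for 2 days in nutrient solution with 10 µM cadmium chloride, either alone or together with reduced glutathione (GSH), the tripeptide thiol from which plants make the cadmium-binding phytochelatins. The labels give the GSH concentration as 100 mM, which is high for roots in hydroponics and could not be checked here, so the dose behind the differences is uncertain. Each group had 3 biological replicates, so 6 arrays were compared. The array carried probes for Arabidopsis thaliana, a relative of oilseed rape, so every gene named here is the Arabidopsis gene its probe set was made for, and oilseed rape copies of that gene were not separated. Plants without cadmium were not analysed here, so all differences are between cadmium with GSH and cadmium alone.

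Of 22746 probe sets, 20318 (89.3%) held a single value on all 6 arrays, to within a range of 0.01 on the log2 scale, and carry no information on the treatment. The other 2428 probe sets varied, and the comparison of gene signals rests on them. The median log2 signal per array lay at 6.00 on each of the 6 arrays. Among the varying probe sets, the correlation between arrays, taken across probe sets, ran from 0.951 to 0.979 within the cadmium group, from 0.982 to 0.990 within the GSH group and from 0.910 to 0.974 between the groups. The first principal component held 57.1% of the variance and put the 3 cadmium arrays at -8.54, -3.87 and -1.97 and the 3 GSH arrays at 7.03, 3.85 and 3.50. Probe sets are not independent replicates, and the number of arrays limits the precision.

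The comparison addressed how GSH given to the roots alters gene signals while cadmium is present. Genes for a lipid-transfer protein (AT5G05960), a peroxidase (AT4G11290), a ribosomal protein (AT4G26230) and a tubulin (TUB7) had higher values on every GSH array, by 0.47 to 0.93 on the log2 scale, and glutathione reductase (GR1) and AILP1 had lower values, by -0.36 and -0.73, but none passed the adjusted threshold. With limma and Benjamini-Hochberg adjustment, 0 of the 2428 varying probe sets had an adjusted p under 0.05, and the smallest adjusted p was 0.0791. At an unadjusted p under 0.05 there were 312 probe sets (12.9%), 150 higher and 162 lower with GSH, and a plain two-sample test on the same values gave 254 unadjusted and 0 adjusted. The 2 groups did not overlap in 455 varying probe sets (18.7%). Chance gives 10% on average over the 10 possible splits of the arrays. A single split can lie well away from this average, because probe sets are not independent. A difference of 2-fold or more was seen in 14 varying probe sets, 4 higher and 10 lower with GSH.

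The 12 genes with the smallest unadjusted p among those with higher values in every GSH array are described first, and each is not significant after adjustment. AT5G05960, of the lipid-transfer protein family, stood at 6.64 ± 0.19 (SD, n = 3) with cadmium alone and at 7.57 ± 0.11 (SD, n = 3) with GSH. Its log2 difference was 0.93, with a limma 95% interval from 0.66 to 1.21 and an adjusted p of 0.136. The intervals and SEs of the named genes take no account of how the genes were chosen, so the differences may be overstated. AT1G48750, of the same family, differed by 0.37 (SE 0.07). AT1G73600, a methyltransferase of the route to phosphocholine, stood at 5.77 ± 0.07 (SD, n = 3) with cadmium alone, not above the highest bacterial control set (6.05), and at 6.76 ± 0.40 (SD, n = 3) with GSH, so the size of its difference is not given. AT4G11290, a class III peroxidase, differed by 0.62 (SE 0.09). Cell wall and cytoskeleton genes were AT1G04680, a pectate lyase, with 0.46 (SE 0.09), TBL36, of a family that acetylates wall polysaccharides, with 0.29 (SE 0.05), and TUB7, a beta-tubulin, with 0.47 (SE 0.08). AT4G26230, a protein of the large ribosomal subunit, differed by 0.53 (SE 0.09), and AT4G12600, of a ribosomal protein family, by 0.47 (SE 0.09). The chloroplast gene psbZ, for a subunit of photosystem II, differed by 0.32 (SE 0.06). AT1G52820, of the 2-oxoglutarate-dependent oxygenases, was not above 6.05 with cadmium alone (5.98) and stood at 6.17 with GSH. AT3G09750 was not above it in either group, at 5.72 and 5.84. Over these 12 genes the adjusted p ran from 0.136 to 0.219.

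The corresponding 12 genes with lower values in every GSH array were also not significant after adjustment, with adjusted p from 0.0917 to 0.228 in limma. AT1G15740 had the smallest, 0.0917, and stood at 7.75 ± 0.06 (SD, n = 3) with cadmium alone and 7.33 ± 0.05 (SD, n = 3) with GSH. GR1, a glutathione reductase that returns oxidised glutathione to its reduced form, stood at 7.91 ± 0.10 (SD, n = 3) with cadmium alone and 7.56 ± 0.11 (SD, n = 3) with GSH. Its log2 difference was -0.36, with a limma 95% interval from -0.54 to -0.17. AILP1, of a family first described as induced by aluminium, differed by -0.73 (SE 0.13). ARL, a gene of organ growth, differed by -0.70 (SE 0.16), and AT1G16670, a receptor-like kinase, by -0.51 (SE 0.12). AT4G01700, of the chitinase family, differed by -0.29 (SE 0.06) and AT4G33420, a class III peroxidase, by -0.14 (SE 0.03). AT2G38640 stood at 6.23 with cadmium alone and AT2G43320 at 6.24, and with GSH both were not above the highest bacterial control set, at 5.97 and 6.03. The other members were AT5G05320 with -0.12 (SE 0.03), AT3G03180 with -0.11 (SE 0.02) and AT4G35750 with -0.08 (SE 0.02).

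**Figure D1:**
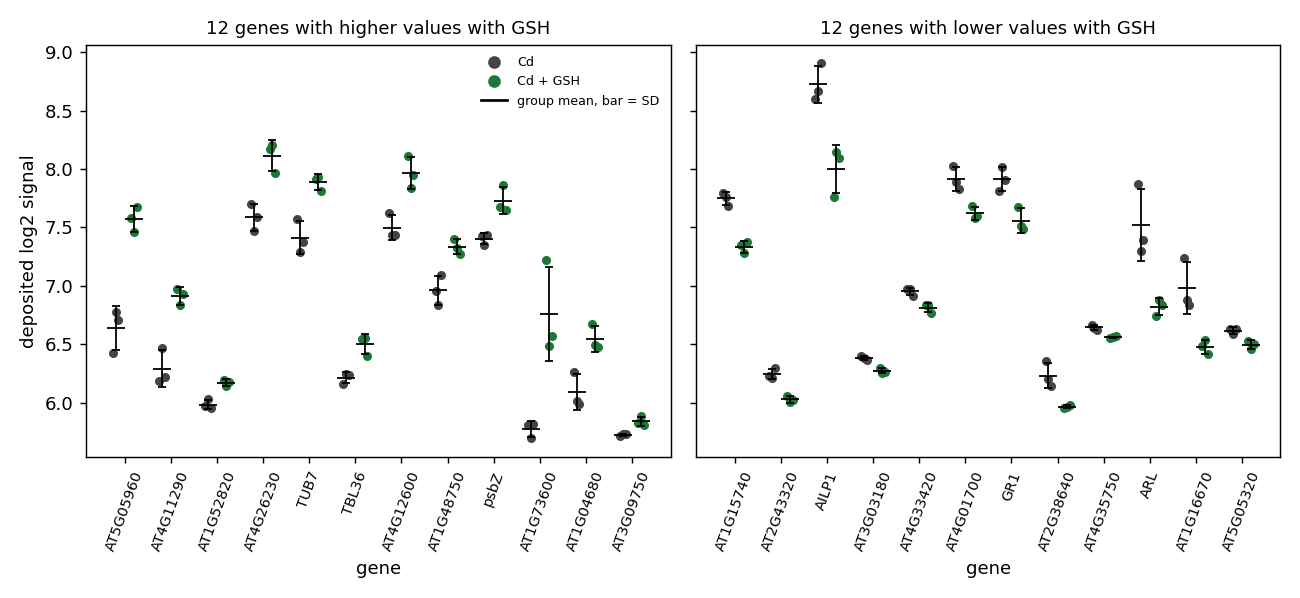
Deposited log2 signal (vertical axis) of the 12 genes with higher and the 12 genes with lower values with GSH (horizontal axis), with a point per array, grey for cadmium alone and green for cadmium with GSH, and group means with SD as black bars. The groups do not overlap in any of the 24 genes because the genes were chosen that way, and AT5G05960 moves from 6.64 to 7.57.

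Some larger differences lay outside this choice and were named after their values were seen, as the genes with the largest differences among those whose groups did not overlap. AT4G27450, related to AILP1, stood at 10.46 ± 0.27 (SD, n = 3) with cadmium alone and at 8.58 ± 1.04 (SD, n = 3) with GSH, a log2 difference of -1.88 whose limma 95% interval ran from -3.24 to -0.52. AT3G15450, of the same family, differed by -0.79 (SE 0.23). ALDH7B4, an aldehyde dehydrogenase of stress responses, differed by -1.28 (SE 0.43), and MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, by -0.87 (SE 0.34). AT1G20380, a prolyl oligopeptidase, differed by 0.97 (SE 0.31). AT1G52790, of the 2-oxoglutarate-dependent oxygenases, was not above the highest bacterial control set with cadmium alone (5.83) and stood at 6.85 with GSH. The differences of 3 of these genes rested in part on single cadmium arrays: MCCA was at -0.51 without cadmium replicate 2, ALDH7B4 at -0.84 without the same array and AT1G20380 at 0.62 without cadmium replicate 1. AT4G27450 was at -1.28 without GSH replicate 1. The other 4 of the 10 genes taken by size had an unadjusted p above 0.05. They were AT4G36500 with -1.14 (SE 0.58), AT1G20270 with -0.97 (SE 0.39), AT5G14700 with -0.83 (SE 0.46) and the peroxidase PRXR1 with 0.78 (SE 0.35), and without cadmium replicate 1 they were at -0.49, -0.64, -0.30 and 0.48. The 10 genes had adjusted p from 0.248 to 0.519 in limma.

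When only the 1516 probe sets ranging by over 0.1 were tested, a limit chosen after seeing the data, limma called 5. AT5G05960 and 2 probe sets unnamed in the annotation used here, 246580_at with 0.74 and 257816_at with 0.35, were higher with GSH. AT1G15740 was lower, and so was the unnamed probe set 264809_at, at -1.66. The adjusted p of 264809_at was 0.0195 and that of each of the other 4 was 0.0474. A limit on the range keeps probe sets partly for the difference between the groups, so these 5 calls depend on that limit.

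The fit planned before the data were examined took in all 22746 probe sets and called 42, 26 higher and 16 lower with GSH. None of the 42 was among the varying probe sets, and the largest of their log2 differences was 2.0e-09, the size of rounding in the deposited values. These calls are therefore given as a count and no gene is named from them.

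The 18 lists of genes fixed beforehand held 409 members, of which 46 could be matched to a probe set with exactly 1 gene name and 9 of those varied. Over the 13 lists with at least 2 matched members, 0 had an adjusted p under 0.05 in limma's camera test with a preset correlation of 0.01. The smallest adjusted p was 0.0739 there, 0.320 with an estimated correlation and 0.0576 in fry. At an unadjusted p under 0.05 camera gave 3 lists, glucosinolate synthesis, sulfate uptake and reduction, and oxidative signalling, of which the first 2 had no varying member. The sulfate list had 3 of 21 planned members matched, none of them a sulfate transporter. Unmatched members were not tested, and some may lie among the unnamed probe sets.

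In the list of glutathione and cysteine metabolism, 2 of 26 planned members were matched, neither of them a gene of GSH or phytochelatin synthesis. GR1 alone varied. Over all probe sets 0 members passed, and 1, GR1, passed when adjusted over the list alone. That adjustment covered only the 2 matched members, 1 of them constant, so it corrected little. In the fit of varying probe sets GR1 was the single member left. Its limma adjusted p over all varying probe sets was 0.219. Of 12 matched glutathione S-transferases, which conjugate GSH to electrophiles, 3 varied. They were GSTU25 with -0.11 (SE 0.05), GSTU27 with 0.05 (SE 0.06) and ATGSTF13. The last was not above the highest bacterial control set in either group (5.98 and 5.94). Of the 12, 0 passed over all probe sets or adjusted over the list alone. Of 3 matched oxidative signalling genes, the transcription factor WRKY6 varied and differed by -0.39 (SE 0.10). It did not pass over all probe sets, nor, in the planned fit, when adjusted over the list alone. In the fit of varying probe sets it was the single member left, so adjustment over the list alone changed nothing and it passed there. Sulfur starvation had 1 varying member of 2, AT1G04770 with -0.07 (SE 0.05), and metal handling 1 of 3, the metal transporter ZIP9 with 0.04 (SE 0.08). CCR2 of the lignin list differed by 0.02 (SE 0.02) and the expansin EXPA18 of the root hair list by 0.03 (SE 0.07). For these 4 lists 0 members passed over all probe sets or adjusted over the list alone.

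The 3 matched genes of sulfate uptake and reduction (APS3, APS4 and SIR), the 3 of iron deficiency, the 3 of antioxidant proteins, the 3 chaperones, the 2 of glucosinolate synthesis, the 4 markers of green tissue and the single marker of dividing cells held a single value on all arrays. For these genes the deposited values cannot show a response in either direction. In the glucosinolate list 1 member passed when adjusted over the list alone, on a difference of rounding size. The lists of jasmonate, endodermal barrier, vascular and nitrogen genes had no matched member.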

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

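The tests of the paired control probe sets and of the actin and ubiquitin ends were chosen after those values were seen; the others in this part were set out before their results were seen. Among the control probe sets, which no comparison used, 1 of 2 probe sets for the 3' end of actin was higher on every GSH array than on any cadmium array, by 0.22 on the log2 scale, while the other was constant at 7.67. A set for the middle of ubiquitin separated the groups the other way, by -0.23. Of the 25 varying control probe sets, only these 2 separated the groups. That share is no larger than the 10% that chance gives on average. Among the varying tested probe sets the share was 18.7%. The difference between the varying 3' actin set and its 5' partner can measure how far labelled RNA reaches along the transcript. It was higher with GSH by 0.21, at 1.45 ± 0.07 (SD, n = 3) against 1.24 ± 0.05 (SD, n = 3). The 5' set ranged by only 0.05 and differed by 0.01, so this 0.21 largely restates the 0.22 of the 3' set. The exact permutation p for the actin 3' to 5' difference was 0.1, the smallest 3 arrays against 3 can give.

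Most probe sets held a single value on all 6 arrays. Of 9 parts of spiked-in control transcripts read by 2 probe sets, 7 had a first set ranging by over 0.1 and a second set that was constant, although both read the same transcript on the same arrays. The 3' end of bioD, for example, ranged by 0.84 in one set and by 3.0e-08 in the other. A low signal as the whole cause is argued against by the brightest 10% of probe sets, 66.0% of which were constant. A candidate explanation is the unstated probe-set summary; no biological explanation was tested, and constant values may therefore hide real differences between the groups.

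The 312 varying probe sets with an unadjusted p under 0.05 were set against 3 technical explanations. Splitting the arrays by the level of the spiked-in controls gave 122, which argues against that level as the cause. Without cadmium replicate 1, the array farthest out on the first component, 13.6% of varying probe sets still had a p under 0.05. The 3' to 5' signal stays open and cannot be told apart from the treatment. The actin 3' to 5' difference separated the groups by 0.21, through its 3' set, and that of ubiquitin did not. Other control pairs did not show this rise, though at least 1 set of each was constant. Another ubiquitin 3' set differed by -0.19, with overlapping groups, and a GAPDH 3' set by 0.002, each with a constant 5' partner. Only 1 of the 10 splits of the arrays, the real one, gave as many as 312, and the highest other gave 190; 10 splits are too few for a share under 0.05, and an effect of GSH also stays open.

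For the 42 calls of the planned fit, each of the 10 splits gave at least as many, and the highest other gave 78. The count of 42 therefore does not set the real grouping apart from the others.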

How the results depend on the processing

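The fits restricted by range, and all alternatives run on the varying probe sets, were chosen after seeing the data. The planned count of 42 (26 higher, 16 lower) rested on differences of rounding size and moved by over 1.5 times in all settings but 3: 30 (18 higher, 12 lower) with the dimmest 25% of probe sets left out, 31 (19 higher, 12 lower) with 1 probe set per gene and 36 (23 higher, 13 lower) with the floor. It was 0 in total and in each direction with quantile normalisation, the intensity trend with robust eBayes, a 2-fold threshold, the plain two-sample test, and a range over 0.01 or 0.0001. With probe sets under the median signal left out it was 14 (9 higher, 5 lower) and with a range over 0.1 it was 5 (3 higher, 2 lower). Median centring gave 20526 (20361 higher, 165 lower), since its small array offsets shifted every constant probe set alike. Leaving out 1 array gave 129 to 168 in total, 66 to 103 higher and 56 to 72 lower.

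With the replicate number as a replicate block the planned count was 0 (0 higher, 0 lower), and 301 varying probe sets had an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at -0.11, -0.21 and 0.13 across probe sets, within the -0.23 to 0.32 of differently numbered ones. The values thus showed no sign of pairing by number, but 3 arrays per group cannot exclude it.

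Among varying probe sets, 0 passed the adjusted threshold, except for 3 with quantile normalisation, 5 with a range over 0.1 and 13 without cadmium replicate 3 (0 to 13 over the arrays left out). The 312 with an unadjusted p under 0.05 (150 higher, 162 lower) became 140 (69 higher, 71 lower) with 1 probe set per gene, since fewer were tested. They ran from 208 to 338 without 1 array; the lower ones ran from 105, without GSH replicate 1, to 200. The cause was not tested.

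Since only 9 of the 46 matched list members varied, most list medians were held near 0 by constant values, and their stability says little. Of 204 list values under alternatives, 199 stayed on their side of the threshold. The exceptions passed it: with median centring, sulfur starvation at a median of -0.036, glutathione and cysteine metabolism at -0.18 and oxidative signalling at 0.0008; with the floor, glucosinolate synthesis at 0; and without cadmium replicate 2, sulfate uptake at 0, the value (0 to 0) for each array left out. The glucosinolate and sulfate lists had no varying member, so their passing shows no response to GSH. For the other exceptions the cause was not tested. Of the named genes, 33 passed the threshold of the planned fit under median centring, where 20526 probe sets did. The unnamed 246580_at and 257816_at each passed without 1 array. Over the arrays left out, 3 list members near 0 changed sign: the metal transporter ZIP9 (-0.016 to 0.12), EXPA18 (-0.0049 to 0.11) and GSTU27 (-0.0066 to 0.088). Outside the lists, MCCA ran from -1.18 to -0.51, ALDH7B4 from -1.63 to -0.84 and AT1G20380 from 0.62 to 1.19. Signal over background limits many values, since 57.4% of tested probe sets lay no higher than the highest bacterial control set. Of the varying ones, 70.9% lay above it.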

Other observations

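The 4 lists in this part were written after the data were seen, and so were the tests of the chloroplast list. Of 64 chloroplast-encoded genes in the annotation, 15 varied and all 15 had a positive log2 difference, with a median of 0.14 (range 0.02 to 0.32), and 6 had an unadjusted p under 0.05. Their values had been seen before the list was written, psbZ among them by its p, and the median of the other 14 was 0.13. ndhE was not above the highest bacterial control set in either group. The varying actin 3' to 5' difference, a possible sign of RNA quality that rests on its 3' set, was also higher on all GSH arrays, by 0.21. The members with the largest differences were psbZ with 0.32, atpE with 0.28, ccsA with 0.25 and psbC with 0.24. The median was 0.13 with quantile normalisation and 0.14 with median centring, and 0.09 to 0.22 with 1 array left out. Since the list was written after its values were seen, it is no independent evidence of its direction, and the same holds for its camera adjusted p, 1.06e-06 at a preset correlation and 0.142 with an estimated correlation. Only the real one of the 10 splits gave a median as far from 0, 0.14, and the highest other gave 0.13; 10 splits are too few for a share under 0.05.

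In the family related to AILP1, 3 of 5 members varied, and AT4G27450, AT3G15450 and AILP1 had differences of -1.88, -0.79 and -0.73. All 3 had been seen before the list was written, so the list is no independent evidence of its direction. GSH replicate 1 stood apart, at -1.05 relative to the mean of all arrays against -0.32 and -0.32 for the other GSH arrays. It had the highest actin 3' to 5' difference, 1.51, but GSH replicate 2 was close, at 1.48. Among genes of branched-chain amino acid breakdown, 5 of 8 varied and all 5 had negative differences, MCCA -0.87, IVD -0.29, ALDH6B2 -0.25, MCCB -0.04 and ETFQO -0.02. MCCA and ALDH6B2 had been seen beforehand, and the other 3 had an unadjusted p above 0.05. With an estimated correlation the adjusted p was 0.142 for each of these lists. Cadmium replicate 2 stood apart in the branched-chain list, at 0.41 against 0.10 and -0.07 for the other cadmium arrays. The actin 3' to 5' difference, higher by 0.21 on the GSH arrays, moved with the groups beside both of these lists as well. The median of the branched-chain list was -0.25 and ran from -0.27 to -0.08 with 1 array left out.

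Cytosolic ribosomal proteins, components of the translation machinery, had 55 varying members of 116 in the annotation. Of these, 51 were higher with GSH, with a median log2 difference of 0.11. An unadjusted p under 0.05 was seen in 6 of the 55, a share no larger than the 12.9% of all varying probe sets. The camera adjusted p was 1.63e-07 at a preset correlation, and the p was 0.273 with an estimated correlation. A trend with signal level is argued against by the list median's place at the 99.99th percentile of 10000 level-matched random lists, and the median was 0.11 without AT4G26230, the member seen before the list was written. Of the 10 splits, 3 gave a median as far from 0 as the 0.11 of the real one, the highest other being 0.21. Other groupings of the same arrays thus gave as large a median, so its size does not set the real grouping apart. Cadmium replicate 1 lay with the GSH arrays, at 0.09 above the mean of all arrays against -0.16 and -0.15 for the other cadmium arrays, and without it the median was 0.21. The varying actin 3' to 5' difference, a possible sign of RNA quality that rests on its 3' set, was higher on all GSH arrays by 0.21. GSH replicates 1 and 2 had the highest values of both measures, the actin difference (1.51 and 1.48) and the list (0.13 and 0.10). Cadmium replicate 1 had the highest of the cadmium arrays on both. GSH replicate 3 broke this order, with a higher actin difference than cadmium replicate 1 (1.37 against 1.29) but a lower list value (-0.01 against 0.09). RNA quality stays open for this list. A response of the translation machinery to GSH may be present, but the spread among cadmium arrays is as large as the difference between groups.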
